A study of Mus musculus with 7 samples.

How the data were processed

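Total RNA of MIN6 cells was labelled with Cy3 from 100 ng of RNA and hybridized to 1-colour Agilent mouse arrays, per the labels' protocols. The deposited scanner files hold spot intensities from Agilent Feature Extraction. Per the file headers, the processed intensity of each spot was background-subtracted and detrended within its array, and the median spot and local background intensities are raw. The file headers give software version 11.5.1.1, while the submitters' processing notes give 10.5.1.1. The flags used, deposited with the intensities, say whether a spot is a control, positive and significant, well above background, saturated or an outlier. The authors' value table holds 1 log2 value per probe (56605 probes). Each of its columns correlated with log2 intensity of its own array at 0.9996 or more across probes, and all columns had a median of 4.438, so the values are quantile normalized, not centred per gene, and run in the same direction. The tool behind that table is not given in the sources used here.

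Samples were grouped as vehicle (3 arrays) and MPE (4 arrays) from the labels. The position on the slide came from the file headers. Control spots and 611 outlier-flagged spot values were left out, and no spot was saturated. Log2 processed intensities were averaged over the spots of a probe and reduced by the array's 75th percentile over all non-control probes. All levels are therefore log2 values relative to that percentile. Averaged over the arrays, more probes were well above background than not. On 3 MPE arrays they were slightly fewer than the others, from 49.4%, so the percentile over probes detected on all arrays was added as an alternative. Probes well above background on at least 3 arrays were kept (28874 probes). The files used here carry accessions and no gene names, so symbols came from a RefSeq gene table of the assembly GRCm38.p6, used for names only. Of 56605 probes, 32994 matched a symbol and the others kept the file's name. A gene with several probes was represented by the probe with the highest mean over all arrays, which left 22060 genes, 13653 of them with a symbol. Among the named genes the probes of Abcc8, Kcnj11, Rela and Oxsm gave differing sizes, from -0.06 to 0.00, -0.01 to 0.11, 0.05 to 0.15 and -0.37 to -0.11 on the log2 scale.

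MPE was compared with vehicle by lmFit and eBayes in limma 3.58.1 under R 4.3.3, with treatment as the only term and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists with at least 5 measured members. The number of detected probes was compared by an exact permutation test. A probe not well above background on every array of a group has only a bound there, and its change is given as at least that many fold. The groups, the main tests, the lists and most alternatives were fixed before the data were examined, and the alternatives added later are named as such with their effects. Genes named in the text were the called genes with a gene symbol and non-overlapping groups (up to 10 per direction), up to 2 passing members per direction of lists that were called or held at least 3 passing members, and 18 genes of beta-cell function, NF-kB signalling, stress and proliferation named in any case. Other genes were chosen after their values were seen, mostly for a small p within their list or among all genes. Gcg was not chosen for its p.

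The alternatives were median and quantile scaling, no filter or a filter on all 7 arrays, the authors' value table, the mean or the lowest probe of a gene, a trended robust variance, array weights, the replicate number or the slide column as a block, each array left out, stricter thresholds, and for lists an estimated correlation and fry. Normexp with an offset of 50 was run on median spot intensity in place of the mean spot intensity planned, which the files used here do not hold. The fit was tested on simulated data made from the gene means and spreads of these arrays, with noise independent between genes and genes changed by known folds. In 10 simulations, 88 of 218600 unchanged genes were called. The number of arrays limits the precision.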

Results

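Gene expression was measured in MIN6 cells, a mouse pancreatic beta-cell line that makes and secretes insulin, after 3 days with a polysaccharide extract of Maidong (MPE) or with phosphate-buffered saline as vehicle. The vehicle group held 3 arrays and the MPE group held 4 arrays, each hybridized with Cy3-labelled RNA of 1 sample. The culture notes list MPE concentrations up to 50 μg/mL, and the labels do not say which was used for the arrays. Nor do they say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. All 7 arrays lay on 1 slide, with the vehicle arrays in its first row and the MPE arrays in its second row, so that slide row and treatment cannot be told apart. Between 27944 and 30122 of 56605 probes per array were well above background. The correlation across genes between arrays was 0.995 to 0.997 within vehicle, 0.991 to 0.994 within MPE and 0.991 to 0.995 between the groups. No pair of arrays was identical.

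The comparison of MPE with vehicle asks which transcripts differ in beta cells after 3 days with the extract. No gene that defines beta cells passed the test for a difference. The insulin genes Ins1 and Ins2 were among the brightest genes on every array, and their MPE levels were 0.900 times (95% interval 0.755 to 1.07) and 0.881 times (0.744 to 1.04) the vehicle levels. The beta-cell transcription factors Pdx1, Mafa and Nkx6-1 stood at 0.957, 0.955 and 0.987 times vehicle. The potassium-channel subunits Abcc8 and Kcnj11, which couple glucose metabolism to insulin release, stood at 0.958 and 1.08 times. The incretin receptor Glp1r stood at 0.949 times, with a wider interval of 0.717 to 1.26. The glucose transporter gene Slc2a2 was not well above background on any array. Each of these genes that was tested had an adjusted p of 1 by limma's moderated test.

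The named genes of NF-kB signalling, stress and proliferation did not pass either. The NF-kB subunits Nfkb1 and Rela stood at 0.960 and 1.04 times vehicle, their inhibitor Nfkbia at 0.993 times and the kinase Ikbkb at 0.976 times. The cytokine Il1b stood at 0.994 times (0.855 to 1.16), and the chemokine Ccl2 was not well above background on any array. The stress transcription factor Ddit3 stood at 1.06 times (0.866 to 1.30) and the proliferation marker Mki67 at 0.919 times (0.823 to 1.03). All 16 tested genes that had been named in advance had 95% intervals inside 1.5-fold in both directions, and the smallest unadjusted limma p among them was 0.112, for Mki67. The direction of 13 of them was lower and of 3 higher. With each array scaled to its median in place of its 75th percentile, Rela turned from 0.05 to -0.02 on the log2 scale. That scaling shifted all genes alike, with their median going from -0.016 to -0.086, so the turn is not particular to Rela.

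**Figure D1:**
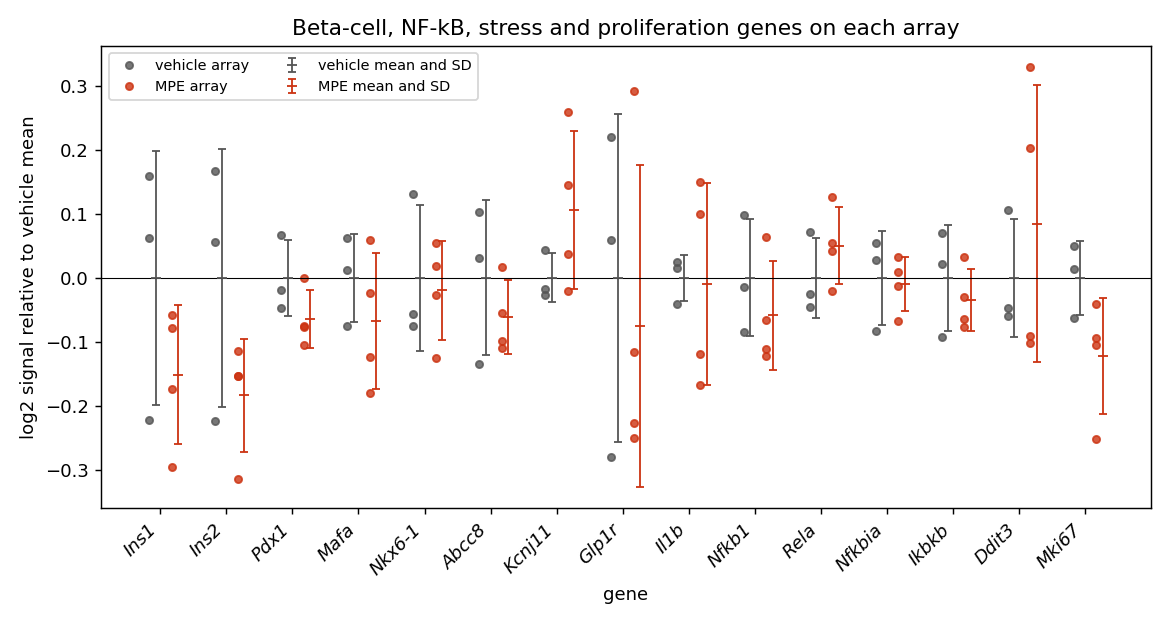
Levels of 15 genes named in advance, on each array: the vertical axis gives the log2 signal relative to the mean of the 3 vehicle arrays and the horizontal axis the gene, with grey points for vehicle arrays, red points for MPE arrays, and bars for the mean and SD of each group. The MPE mean lies between 0.881 and 1.08 times the vehicle mean for all 15 genes.

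At the level of gene groups, none of the 29 lists passed the test for a difference between MPE and vehicle. They covered beta-cell function, inflammation, stress, metabolism, growth and markers of other cell types. The list medians lay between -0.08 and 0.02 on the log2 scale, and 0 of the 736 measured members passed limma's adjusted threshold over all genes. At an unadjusted p under 0.05, no list held more than 1 member in a direction, except for 3 higher in growth factors, matrix and TGF-beta and 4 lower in the stromal, endothelial and immune markers. In beta-cell identity genes, 16 of 35 measured members were higher and 19 lower, none past the threshold. In insulin granule and exocytosis genes, 12 of 39 were higher and 27 lower, with a median of -0.04. The exocytosis SNARE protein Snap25 had the smallest p of that list, with a log2 difference of -0.27 (SE 0.10, limma adjusted p = 1). In NF-kB and inflammatory genes, 15 of 32 were higher and 17 lower. Higher and lower members split 15 to 17 in ER chaperones and the unfolded protein response, and 11 to 30 in mitochondrial respiration. The DNA replication list split 20 to 23, and the cell cycle and mitosis list 12 to 22. Camera called 0 lists higher and 0 lower, also without adjustment. The smallest camera p was 0.0515, for the housekeeping references, whose median was -0.08. Its adjusted p was 0.736, and with an estimated correlation the adjusted p = 0.949. With estimated correlations camera also called 0 lists higher and 0 lower, and fry's smallest adjusted p was 0.953. Camera's direction was up although the median lay below 0 for beta-cell identity, NF-kB and inflammatory genes, ER chaperones, DNA replication, lysosome and autophagy, immediate-early genes, growth factors and matrix, and other islet cell types. Of these, DNA replication and the growth factors and matrix had means above 0 (0.01 and 0.16). The latter mean was 0.00 over the 24 members other than the matrix protease gene Mmp2, which was not well above background on any vehicle array. Without MPE replicate 1, the array on which it was not well above background either, Mmp2 was called higher (limma adjusted p = 0.0126). The interferon-stimulated genes had a median of 0.01 and a mean of -0.00 with the direction up.

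Adjusted over the list alone, 1 of the 29 lists held a passing member. This was the sodium-glucose cotransporter gene Slc5a10, from the list of genes normally held low in beta cells or raised on dedifferentiation. Its log2 difference was -0.48 (SE 0.06), with all 4 MPE arrays below all 3 vehicle arrays and an adjusted p over the list alone of 0.00283. Over all genes tested, its limma adjusted p was 0.316. The other 18 measured members of that list did not pass over the list alone. Adjustment over a list alone makes no allowance for the 29 lists. At 0.05 per list, 1 list with a passing member is no more than chance alone would give. Among markers of cell types that a pure beta-cell line should lack, the stromal, endothelial and immune list had 12 measured members and a median of -0.04. The myeloid integrin Itgam, the smooth-muscle gene Tagln and the endothelial gene Esam had log2 differences of -0.35, -0.34 and -0.21, each with an adjusted p of 0.0544 over the list alone. The alpha-cell hormone Gcg, which these cultures also expressed, stood at -0.00 (SE 0.07) on the log2 scale. In the exocrine and duct list the median of 9 members was 0.02, and the lipase gene Cel had a log2 difference of 1.63 (SE 0.57) that did not pass.

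**Figure D2:**
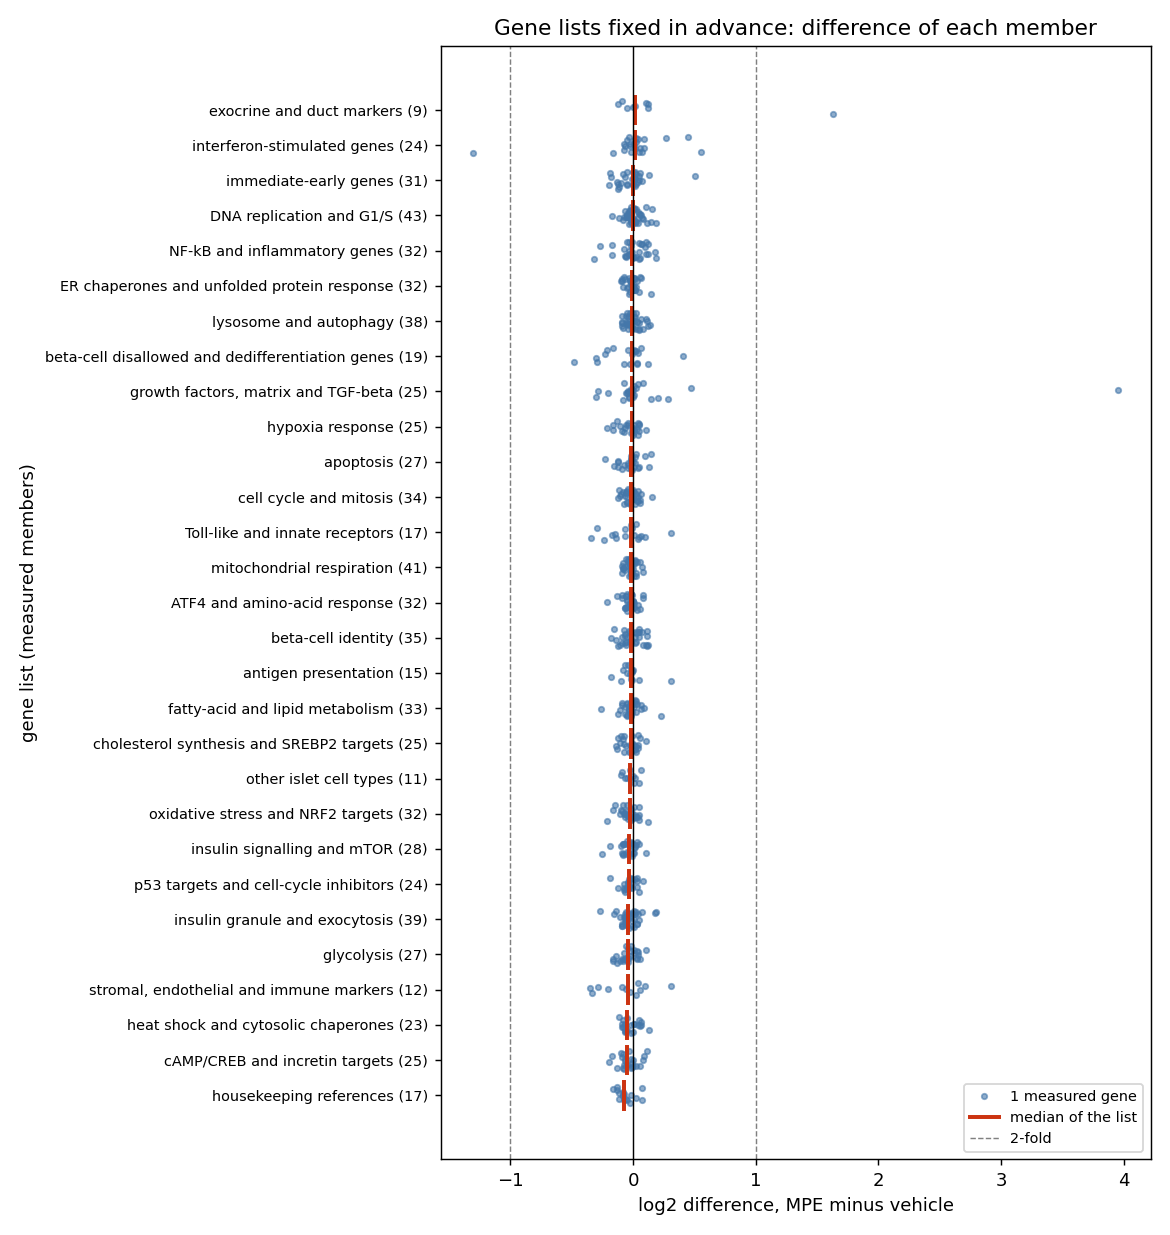
Log2 difference between MPE and vehicle (horizontal axis) of every measured member of the 29 gene lists (vertical axis, with the number of measured members). Each point is 1 gene, the red bar is the list's median and the dashed lines mark 2-fold. List medians lie between -0.08 and 0.02.

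Across all 22060 genes tested, limma called 1 gene higher and 0 genes lower with MPE at an adjusted p under 0.05. The called gene was Olfr867, an odorant receptor gene measured by 1 probe, with an adjusted p of 0.00490. It was not well above background on any vehicle array and well above background on all 4 MPE arrays, so it was at least 3.06-fold higher with MPE. That bound sets the mean of the MPE arrays against the lowest signal well above background on each vehicle array, or the probe's own where that was higher. Its vehicle log2 values (-6.76, -6.874 and -6.735) nearly equalled those of another odorant receptor gene, Olfr390 (-6.763, -6.884 and -6.732). They thus lay at each array's floor, and the adjusted p of Olfr867 rests partly on the spread of that floor. Its probe also passed the filter through the MPE arrays alone. The call was lost with the slide column as a block (adjusted p = 0.0557, and 0.00215 with a trended robust variance added), with normexp background correction (0.416), which adds an offset of 50 to every signal, without vehicle replicate 1 (0.0880) and without vehicle replicate 3 (0.0778). With the replicate number as a block it was lost as well. MPE replicate 3 was alone in its slide column, so the column block took no information on MPE from it. Leaving out that array without a block gave the same fitted difference and kept the call (limma adjusted p = 0.00124). The replicate block likewise took none from MPE replicate 4, whose number no vehicle array shares. Across the settings tried, the adjusted p of Olfr867 ranged from 0.0009 to 0.416. Its fitted log2 difference, which is no bound because the vehicle arrays are at background, was 3.75, and it was 3.59 with the slide column as a block and 0.67 with normexp. Its spot lay in row 3 of the array, in a region where isolated bright spots were common on all MPE arrays.

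At an unadjusted p under 0.05, limma counted 167 genes higher and 740 lower, where chance alone would give 552 in each direction. With median scaling the split was 67 higher and 1328 lower, with normexp 159 and 1184, and with quantile normalization 124 and 1063. With the slide column as a block, which leaves MPE replicate 3 out of the comparison, it was 279 higher and 919 lower. That fit called 0 genes in each direction. The arrays of both groups did not overlap for 4.53% of the genes, against 5.71% expected by chance. Of the genes with the smallest unadjusted p, chosen after their values were seen, the mitochondrial fatty-acid synthase Oxsm had a log2 difference of -0.37 (SE 0.06, limma adjusted p = 0.605), and its other probe gave -0.11. The carboxypeptidase Cpa4 had -0.44 (SE 0.08, adjusted p = 0.684). The glutamate receptor Gria1 was at least 1.28-fold higher in vehicle (adjusted p = 0.539) and not well above background on any MPE array. Eif4e1b and Arhgef26 had smaller unadjusted p than these genes, without passing, and were also not well above background on any MPE array. Their bounds, at least 0.907-fold and 0.782-fold, show no difference. The helicase gene Dhx8, well above background on all 7 arrays, was higher with MPE by 0.42 (SE 0.08, adjusted p = 0.803).

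The 95% interval of the difference lay within 2-fold in both directions for 94.2% of the genes tested and within 1.5-fold for 80.7%. Of the 736 measured list members, 725 had intervals within 2-fold and 691 within 1.5-fold. In simulated data with the spread of these arrays, 22060 genes and noise independent between genes, the same test called 54.6% of genes changed by 1.5-fold, 82.6% of those changed by 2-fold and 97.6% of those changed by 4-fold. These shares rest on 500 changed genes per fold over 10 simulations. The adjusted threshold is easier to pass when many genes change together, so with fewer changed genes the shares would be lower. The simulated noise was normal, and each change was added in full, also to genes near background. A real change may not show in full there, so the shares may be too high for dim genes. Noise shared between genes, as along the slide columns, was not simulated.

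**Figure D3:**
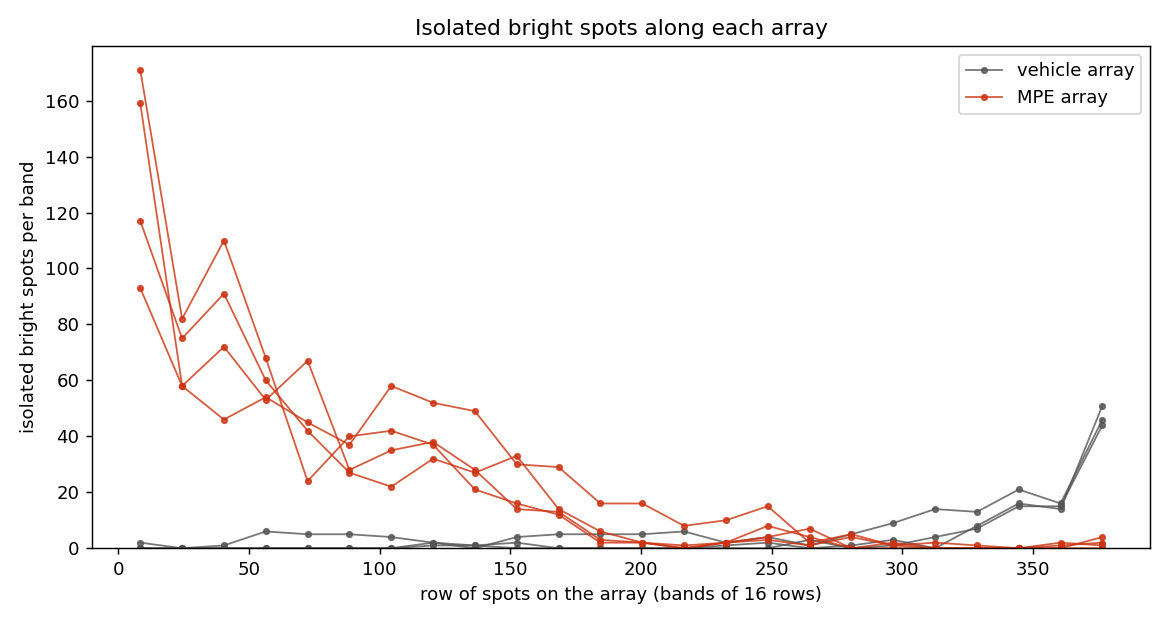
Isolated bright spots, well above background and over 8-fold above the mean of the spot's 3 lowest arrays, counted in bands of 16 rows along each array. The horizontal axis gives the row of spots and the vertical axis the spots per band, with red lines for the 4 MPE arrays and grey lines for the 3 vehicle arrays. MPE arrays held 525 to 696 such spots, mostly at low row numbers, and vehicle arrays 92 to 181, mostly at high row numbers.

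Fewer probes were well above background on the MPE arrays. The mean was 28180 ± 246 (SD, n = 4) with MPE and 29770 ± 320 (SD, n = 3) with vehicle, and every MPE array lay below every vehicle array (exact permutation test, two-sided, p = 0.0286 over 35 splits, the smallest these splits allow). Doubling the one-sided exact p gave 0.0571. With 1 threshold for all arrays the direction turned, to 251 more probes with MPE on the scaled signal (exact permutation p = 0.171) and 875 more on the unscaled signal (exact p = 0.114). The lowest signal counted as well above background was 20.6 to 24.4 on the MPE arrays and 12.6 to 15.5 on the vehicle arrays. Before background subtraction, the mean raw signal of the negative-control spots was 32.7 ± 0.29 (SD, n = 4) with MPE and 29.8 ± 0.85 (SD, n = 3) with vehicle. The lowest signals given above are background-subtracted, so these measures cannot be set against each other.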

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

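The tests of where bright spots lie and of lower genes by part of the array were chosen after the result was seen, and the others before.

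Isolated bright spots, over 8-fold above the mean of the spot's 3 lowest arrays, numbered 606 ± 76.9 (SD, n = 4) on MPE arrays and 124 ± 49.2 (SD, n = 3) on vehicle arrays, and the spot of the called gene Olfr867 was bright on all 4 MPE arrays. In the low-numbered rows of the array lay 95.2% of these spots on MPE arrays (91.0% to 97.7% per array), and on vehicle arrays 3.26%, 4.00% and, on replicate 3, 21.6%. Where 1 probe of a gene was bright, 7.12% of the gene's other probes (46 of 646, exact 95% interval 5.26 to 9.38) lay at least 2-fold above their vehicle mean on the same array, against 3.18% of all named probe values. The other probes were not filtered for detection, so those at background could miss a rise. A probe can also count on several MPE arrays, so the interval is only rough. With these limits, the low share, though above that of all named probe values, argues against transcripts made under MPE as the source of the bright spots as a set. A spot artefact tied to the place on the array is a candidate explanation. By the same rule, counted without a prior prediction, 0 of the 308 negative-control spots were bright on any array. These spots thus gave no sign of an artefact, but their places on the array were not compared. Neighbours of bright spots on MPE arrays had median log2 levels of -1.825 to -1.73, against -2.737 to -2.695 beside other dim spots. On vehicle arrays these were -2.277 to -1.936 against -2.9 to -2.874. Olfr867 itself stays open, because it has 1 probe, and 2 spots were bright on all 4 MPE arrays and no vehicle array, where 0.253 would be expected from the density of bright spots in bands of 16 rows. That expectation takes the arrays as independent within a band, which was not tested. Olfr390, another odorant receptor gene, was also well above background on all 4 MPE arrays and no vehicle array, without passing (limma adjusted p = 0.199).

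At an unadjusted p more genes were lower than higher, and the dimmest of 5 brightness groups held 379 of the 740 lower genes and 89 of the 167 higher ones. The filter can be met by the 3 vehicle arrays alone, whose lowest signals well above background were 12.6 to 15.5, against 20.6 to 24.4 with MPE. Dim genes can thus enter because they are higher in vehicle. The MPE arrays alone can also meet the filter, as they did for Olfr867. With the filter on all 7 arrays 540 genes were lower and 141 higher. Without a filter, which lets in genes above background on no array, 1184 were lower and 11087 higher. The low-numbered rows of the array gave 197 lower and 142 higher genes of 12498, and the high-numbered rows 656 lower and 50 higher of 12381, so that the former held 30.0% of the latter's number of lower genes, which argues against lower transcript levels with MPE alone. Among 91 dim genes with a probe in each part of the array, the log2 difference was lower in the high-numbered rows by a median of -0.13 (65 of 91 genes, exact sign test p = 5.31e-05), so place on the array may contribute for dim genes. For 286 probes with spots in both parts the median was 0.0036, which argues against a place effect for these, of which 4 were dim. Those 4 had a median of -0.20.

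Fewer probes were well above background on the MPE arrays, by -1584 on average. With 1 threshold on the scaled signal for all arrays the difference was 251 probes higher with MPE (-15.8% of its size, exact permutation p = 0.171), and with 1 threshold on the unscaled signal 875 higher (-55.2%, exact p = 0.114).

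A mean of 7.5 of 308 negative-control spots, which the comparison of genes does not use, were well above background on the MPE arrays, and 0 to 5 on the vehicle arrays (exact permutation p = 0.0857). Replicate 4 of the MPE group stood apart for Ssu2, at -3.81 against -4.09 to -4.06 on the other 3 MPE arrays. Chance would give about 3 such outlying arrays over the 60 values checked.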

How the results depend on the processing

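The settings on normexp, parts of the array, the percentile over detected probes, the slide column with a trended robust variance and the doubled p were chosen after seeing the data. The 16 tested genes named in advance passed the threshold in 0 of 387 combinations of gene and setting, with the other sign in 31. For genes higher with MPE, the count of 1 became 0 with normexp, the filter on all 7 arrays, the slide column as a block, the high-numbered rows alone and the replicate block. It became 3 with a trended robust variance, 3 with array weights and 9 with the slide column and a trended robust variance. Leaving out 1 array gave 0 to 3 (0 without vehicle replicate 1 or 3, 2 without MPE replicate 2, 3 without MPE replicate 1, 3 or 4). For genes lower with MPE, the count of 0 became 2 with the lowest probe, 1 with array weights and 2 in the high-numbered rows alone. Leaving out 1 array gave 0 to 1 (1 without vehicle replicate 2 or MPE replicate 2 or 4). Olfr867 was not among the 19713 genes of the filter on all 7 arrays or the 12381 of the high-numbered rows; for the other changes the cause was not tested. Without a filter on dim probes 9619 genes were higher and 349 lower, and 97.7% of these were well above background on no array. Gene lists higher with MPE numbered 0 in every setting, and gene lists lower with MPE 19 without that filter and 0 otherwise. Without it camera's direction turned to lower for 5 lists: beta-cell identity (median -0.0256), ER chaperones and unfolded protein response (-0.0124), DNA replication and G1/S (-0.00979), lysosome and autophagy (-0.00868) and immediate-early genes (-0.000612). Camera sets a list against the other genes, and the median of all genes rose from -0.0159 to 0.0545 without the filter. A list can thus be called lower without falling itself: the beta-cell identity median moved only from -0.0196 to -0.0256. The difference in detected probes per array was -1584 with a doubled p of 0.0571, and -1717 to -1407 on leaving out 1 array, where the splits are too few for an exact p under 0.05. With the replicate block, which leaves MPE replicate 4 out of the comparison, 0 genes were called higher and 0 lower (412 and 1487 at unadjusted p). Same-numbered samples deviated together at 0.247, 0.0509 and 0.413 across genes, and the other pairs of a vehicle and an MPE sample at -0.334 to 0.306. Not every sample correlated best with its own number, so whether the numbers pair the samples is not settled. Signal over background limits what can be said of dim genes.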

Other observations

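More genes differed along the slide than with treatment, in a comparison chosen after seeing the data. With treatment in the fit, the 4 arrays in slide columns 1 and 2 were compared with the 3 arrays in columns 3 and 4. The former were replicates 1 and 2 of each group, and the latter vehicle replicate 3 and MPE replicates 3 and 4. Slide column and replicate number therefore cannot be told apart in this comparison. Limma called 100 genes higher and 273 lower in columns 1 and 2, and 1 gene for MPE in the same fit. The immediate-early gene Ier2 was higher by 0.76 on the log2 scale (SE 0.12, limma adjusted p = 0.0482), with 0.67 within vehicle and 0.82 within MPE. The amino-acid transporter subunit Slc3a2 was higher by 0.31 (SE 0.05, limma adjusted p = 0.0478), with 0.33 and 0.30. The immediate-early genes Fos and Egr1 had differences of 0.93 and 0.92, and the glutathione-degrading enzyme Chac1 had 0.73, without passing (adjusted p = 0.0527, 0.0677 and 0.0561).

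By list, camera called 13 of 29 higher in columns 1 and 2 and 1 lower. With an estimated correlation 0 lists passed, with an adjusted p = 0.378 for ATF4, and fry called 17, without hypoxia (adjusted p = 0.0771), glycolysis (0.0712) and DNA replication (0.0709). By camera with the preset correlation, the ATF4 and amino-acid response list had a median of 0.24 (adjusted p = 1.47e-07), immediate-early genes 0.19 (0.0118) and hypoxia genes 0.15 (0.00654). The housekeeping references were among them, with a median of 0.13 (0.00654). DNA replication was lower, with a median of -0.06 (0.0146).

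A shared state of the cultures or RNAs placed side by side and uneven hybridization are both possible explanations of the column difference. For 34 genes called by 1 probe, it correlated with that of the gene's other probes at 0.423 across genes, which are not independent replicates, with the same sign in 79.4%. This lies between what the explanations predict, so they cannot be told apart. No biological explanation was tested, because the labels give no culture or extraction batch.

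Of the 35 splits of the 7 arrays into 4 and 3, 3 gave as many genes higher as the real split (1 gene, highest other 626) and 7 as many genes lower at unadjusted p (740, highest other 2728), so chance is not excluded for either. The real counts of genes lower, lists higher and lists lower were 0 (highest other 783, 12 and 9), which all 35 splits must reach, so these counts say nothing about chance. The split with 626 and 783 genes set slide columns 1 and 2 against 3 and 4, which points to a structure of the samples or of their hybridization.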
